A study of Anopheles gambiae with 36 samples.

How the data were processed

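Transcript levels were measured in the malaria mosquito Anopheles gambiae on Affymetrix oligonucleotide arrays that also carry probe sets for Plasmodium. The 36 arrays fall into 12 groups of 3. Whole females were sampled without blood and at 3 h, 24 h, 48 h, 72 h, 96 h and 15 d after a blood meal taken on mice. Whole males, larvae of the late instars, and fat body, midgut and ovary dissected 24 h after blood made up the other groups. Per the labels' protocols, each sample of a time point pooled 5 mosquitoes, total RNA was extracted and passed over a column, and biotin-labelled cRNA was made by in vitro transcription. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate cages or cohorts, so p-values measure the spread between these samples.

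Per the submitters' processing notes, the deposited intensity values came from GCOS version 1.1.1, and they are linear probe set signals with 1 column per array. The scaling target, detection calls and masks are not given in the sources used here. The 2% trimmed mean of the signal lay between 500.3 and 500.4 on every array, so the authors' scaling was kept. This scaling makes signals relative: a few abundant transcripts that rise lower the scaled signal of the others. From the arrays' settings files, the scan day, the fluidics position, the hybridization date, the chip type and the solution lot were read. The lot entry held the letters ReIVT on every 72 h and 96 h array and on no other. This mark was read as a repeat of the in vitro transcription.

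The array holds 22761 probe sets, of which 16884 carry a mosquito identifier, 4506 a Plasmodium identifier, 937 an accession and 290 a number, and 144 are controls. The background limit of an array was the 95th percentile of its Plasmodium probe sets, since no mosquito here was labelled infected, and it ranged from 38.0 to 137. Signals below 9.56, the median over arrays of the median Plasmodium signal, were set to that floor before log2. A mosquito probe set was tested if it lay above the limit on all 3 arrays of at least 1 group, which held for 14822. Between 64.0% and 82.6% of the mosquito probe sets lay above the limit on an array, and the number of arrays limits the precision. Where a probe set lay above the limit on no array of the dimmer group, or of 1 of the tissues averaged, its fold is a bound: the brighter group's mean log2 signal is set against the mean log2 of, per array, the higher of the limit and the probe set's own signal, and it is written "at least".

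One limma fit (version 3.58.1, R 4.3.3) with a mean for each of the 12 groups used lmFit and eBayes on all arrays. Each probe set's spread was thus pooled over all 12 groups. The p-values of whole-body comparisons therefore also hold the spread between the tissue arrays, including a fat body replicate that stood apart. With only the compared groups in the fit, 5323 probe sets were called at 24 h against non-blood-fed females, against 5418 in the main fit. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. For the F test over the 7 whole-female groups, the range of group means had to reach 2-fold. Each tissue was set against the unweighted mean of the other tissues. Values with ± are means and SDs of the deposited signal with n = 3 arrays. The comparisons against non-blood-fed females all share the same 3 control arrays. Adjusted p-values are limma's unless another test is named.

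The probe set identifiers are not paired with gene names in the files, and 0 of them matched the 15165 genes of the RefSeq table supplied (assembly idAnoGambNW_F1_1). The design, the naming rule, the gene lists and most of the alternatives were fixed before the data were examined. All gene lists are void for want of names and were not run. The naming rule for that case names the probe sets with the 2 highest and the 2 lowest log2 changes in each comparison, among those with an adjusted p under 0.05 and no overlap between the arrays compared, with probe sets of one cluster counted once. It orders fitted values, so where a fold is a bound it gives no order of the changes. For 3 arrays against 3, chance gives no overlap in 10% of probe sets. The 48 choices so made had limma adjusted p-values of at most 4.27e-05. The chromosome arm is the one written in the identifier.

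Groups of probe sets were therefore chosen after the data had been seen. A tissue set holds the probe sets at least 4-fold above each of the other tissues with an adjusted p under 0.05 in both contrasts: 1441 for ovary, 783 for fat body and 838 for midgut. They name where a transcript was enriched in these 9 arrays and no function. These sets rest on the dissected tissues alone and were followed on the separate whole-body arrays with limma's camera, at a preset correlation of 0.01 and with an estimated correlation, adjusted over 27 tests. Where a scaling moved the median of all probe sets by over 0.1, set medians are given relative to that median. Calls on the X chromosome were set against those on the autosomes with Fisher's exact test, two-sided, adjusted over 24 tests.

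Alternatives changed the normalization, the floor, the filter, the arrays in the fit, the variance model, the fold minimum and a block for the replicate number, and left out each array in turn. Same-numbered arrays did not deviate together, with correlations from -0.07 to 0.08, so the numbers were not treated as pairs. Each group lay within 1 scan day: fat body on day 1, midgut and ovary on day 3, 72 h and 96 h on day 4, and all others on day 2. The scan day could not be fitted as a block, and within-day fits were used where both groups shared a day. For 72 h and 96 h against non-blood-fed females or any other group of day 2, and for fat body against the other tissues, scan day and group cannot be told apart. At 72 h and 96 h the repeat of the in vitro transcription cannot be told apart from the group either.

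The scripts were tested on simulated data with 14822 probe sets. For 24 h against non-blood-fed females, 94.0% of 100 probe sets changed by 3 on the log2 scale and 60.0% of 100 changed by 1.5 were recovered, with 6 false calls. Figures were drawn with matplotlib.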

Results

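The question of the series was how gene expression across the mosquito genome responds to a blood meal, with males, larvae and dissected tissues as further points of reference. Replicate arrays correlated across probe sets with a mean r of 0.940 to 0.969 within each group except fat body, where the mean was 0.866. Probe sets are not independent replicates, so these r values describe the arrays. The share of mosquito probe sets above the background limit ranged from 65.9% ± 0.915 (SD, n = 3) in midgut to 82.1% ± 0.454 (SD, n = 3) at 15 d. The actin control's 3' to 5' signal ratio, a measure of RNA integrity, was 4.05 ± 0.732 (SD, n = 3) in fat body, 2.63 ± 0.445 in males, 2.16 ± 0.266 at 96 h and 2.08 ± 0.223 in non-blood-fed females, against 1.33 to 1.54 in the other groups. The GAPDH control's ratio was also highest in fat body, at 2.87 ± 0.802, but lowest in males, at 0.969 ± 0.142. It was 1.57 ± 0.209 in non-blood-fed females and 1.27 to 1.89 in the remaining groups, so actin and GAPDH did not rank the groups alike. The labels of the 3 h and larvae groups were in doubt, for the correlations given with their comparisons, and these arrays are called "labelled 3 h" and "labelled larvae" throughout.

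Over the whole-female time course, 10705 of 14822 probe sets differed between the 7 groups by the F test. Without the arrays labelled 3 h, the count was 8407. Among the 10705, the highest mean lay at 72 h for 2561, in the arrays labelled 3 h for 2534 and in non-blood-fed females for 2078. The 96 h group held the highest mean of 462 probe sets and the lowest of 319.

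At 24 h after blood, probe sets enriched in the ovary stood higher than in non-blood-fed females, while of those enriched in fat body and midgut more were called lower than higher. Of the 1441 probe sets of the ovary set, 1044 rose, 3 fell and 394 did not pass the test. Their median change was 1.66 on the log2 scale relative to the median of all probe sets (camera adjusted p = 5.13e-26, and adjusted p = 0.202 with an estimated correlation). Of the 783 probe sets of the fat body set, 353 fell, 65 rose and 365 did not pass, with a relative median of -1.02 (camera adjusted p = 3.19e-11, and adjusted p = 0.157 with an estimated correlation). Of the 838 probe sets of the midgut set, 256 fell, 82 rose and 500 did not pass, with a relative median of -0.71 (camera adjusted p = 6.17e-07, and adjusted p = 0.233 with an estimated correlation). In whole bodies scaled alike, a larger share of ovary RNA would by itself lower the signals of the fat body and midgut sets. At this and the other times, a change in tissue share and regulation within a tissue therefore cannot be told apart. Ag.3R.2657.1_a_at, on arm 3R, measured 53800 ± 2020 at 24 h against 18.8 ± 10.1 in non-blood-fed females (SD, n = 3), at least 692-fold higher (limma adjusted p = 2.47e-13). Ag.2R.2.0_CDS_at measured 29600 ± 1180 against 23 ± 16.6, at least 381-fold higher. Ag.3R.780.0_CDS_at fell from 5560 ± 1220 to 15.0 ± 1.85, at least 120-fold lower, and Ag.3R.180.0_CDS_at from 14900 ± 2310 to 41.7 ± 3.61, at least 324-fold lower. The actin ratio was 1.36 ± 0.122 (SD, n = 3) at 24 h against 2.08 ± 0.223 in non-blood-fed females. In total 5418 probe sets were called, 3028 higher and 2390 lower, and 5574 with the arrays of the shared scan day alone. With each array centred on its median, the split was 2331 higher and 3128 lower, because that scaling moved the median of all probe sets from 0.06 to -0.16.

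At 48 h and 72 h the sets had the same directions. The ovary set had 1156 members higher and 9 lower at 48 h, with a relative median of 2.03, and 1196 higher and 12 lower at 72 h, with a relative median of 2.15 (camera adjusted p = 2.02e-29 at both times, and adjusted p = 0.175 with an estimated correlation). The fat body set had 431 members lower at 48 h and 488 at 72 h, with relative medians of -1.21 and -1.43 (adjusted p = 0.0787 with an estimated correlation at both times). In the midgut set 321 members were lower at 48 h and 380 at 72 h (adjusted p = 0.175 and 0.157 with an estimated correlation). At 48 h Ag.2L.1245.0_CDS_at measured 42700 ± 1210 against 19.8 ± 4.49 (SD, n = 3), at least 549-fold higher, and Ag.2R.154.0_CDS_at 21200 ± 1970, at least 271-fold higher. Ag.2L.245.0_CDS_at fell at least 563-fold at 48 h, from 25300 ± 1210 to 29.9 ± 9.79, and Ag.3R.231.0_CDS_at at least 320-fold, from 14500 ± 2310 to 22.4 ± 2.56. At 72 h Ag.3R.855.0_CDS_a_at was at least 88.4-fold higher (6880 ± 354) and Ag.2L.563.0_CDS_at at least 77.6-fold higher (6040 ± 354). Ag.UNKN.186.1_s_at, with no arm assigned, fell from 33500 ± 1970 to 48.0 ± 53.8 at 72 h and lay above the limit on 1 of the 3 arrays there. Ag.3R.180.0_CDS_at was at least 340-fold lower at 72 h. The counts were 6208 at 48 h (3507 higher, 2701 lower; 6333 with the arrays of the shared scan day alone) and 6884 at 72 h (3730 higher, 3154 lower). Median scaling gave 2576 higher and 3824 lower at 48 h, and 2873 higher and 4157 lower at 72 h. The 72 h and non-blood-fed arrays were scanned on different days, and only the 72 h arrays carried the mark of a repeated in vitro transcription. The 72 h females were also older than the non-blood-fed females. Day, labelling, age and group therefore cannot be told apart.

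**Figure D1:**
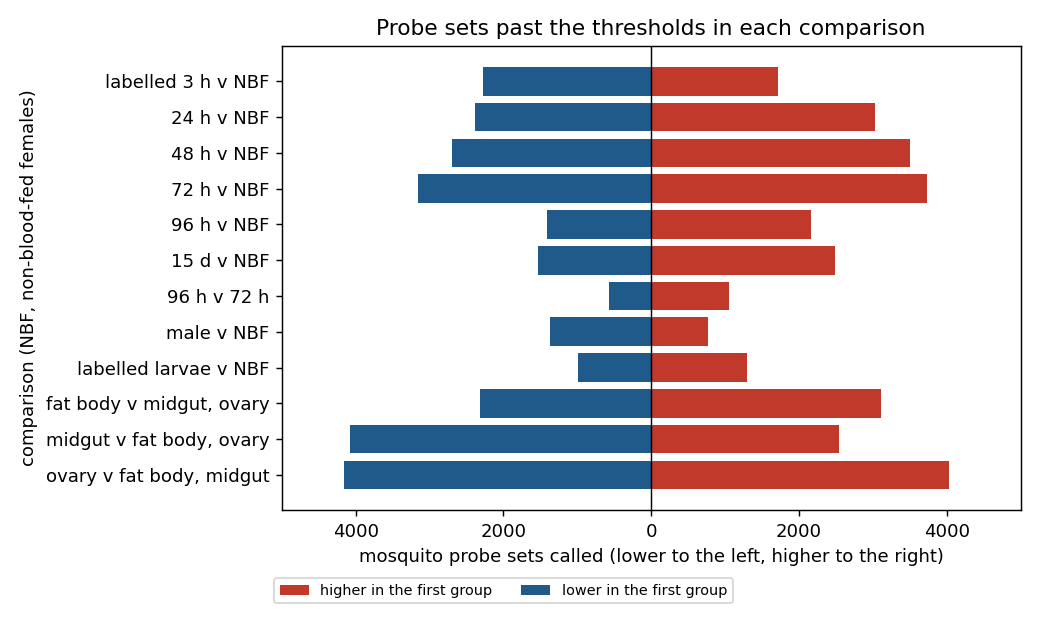
Bars give the number of mosquito probe sets called higher (right, red) and lower (left, blue) in the first group of each of the 12 comparisons, out of 14822 tested. Among the blood-fed groups the count against non-blood-fed females (NBF) is highest at 72 h, with 3730 higher and 3154 lower.

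After egg laying, which the labels place between 72 h and 96 h, the median log2 signal of the ovary set was 9.1 ± 0.19 at 96 h against 9.83 ± 0.05 at 72 h and 7.82 ± 0.07 in non-blood-fed females (SD, n = 3). From 72 h to 96 h, 239 fat body probe sets rose and 7 fell, and 212 midgut probe sets rose and 7 fell, with relative medians of 0.81 and 0.71 (adjusted p = 0.0787 and 0.102 with an estimated correlation). In the ovary set 228 members fell and 8 rose, with a relative median of -0.78 (camera adjusted p = 7.56e-19, and adjusted p = 0.271 with an estimated correlation). Ag.3L.444.0_CDS_at was at least 11.4-fold higher at 96 h, but its 3 arrays spread widely, at 746 ± 757. Ag.2R.1750.0_CDS_at likewise measured 549 ± 417 and was at least 10.4-fold higher. Ag.3L.332.0_CDS_at fell at least 6.48-fold, from 391 ± 197, and Ag.2R.3524.0_CDS_at fell from 514 ± 79.1 to 67.6 ± 69.9, with 1 of 3 arrays above the limit at 96 h. The actin ratio was 2.16 ± 0.266 at 96 h and 1.39 ± 0.0361 at 72 h (SD, n = 3). The comparison called 1635 probe sets, 1059 higher and 576 lower, and 1873 with the arrays of the shared scan day alone. Without replicate 1 of 96 h it called 1080 probe sets, 816 higher and 264 lower.

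Against non-blood-fed females, ovary probe sets were still higher at 96 h (797 of 1441, relative median 1.2, adjusted p = 0.233 with an estimated correlation) and at 15 d (763 of 1441, relative median 1.1, adjusted p = 0.290 with an estimated correlation). In the fat body set 236 members were lower at 96 h and 251 at 15 d (adjusted p = 0.157 and 0.155 with an estimated correlation). The midgut set had 92 members lower and 60 higher at 96 h, and 104 lower and 69 higher at 15 d (adjusted p = 0.421 and 0.483 with an estimated correlation). At 96 h Ag.3R.855.0_CDS_a_at was at least 42.4-fold higher and Ag.2L.1348.0_CDS_at at least 18.7-fold higher, while Ag.X.80.0_UTR_a_at fell at least 155-fold from 8640 ± 296. Ag.3R.231.0_CDS_at fell to 40.9 ± 44.6 at 96 h, with 1 of 3 arrays above the limit. At 15 d Ag.2R.2360.0_CDS_s_at was at least 24.7-fold higher and Ag.2L.1348.0_CDS_at at least 22.9-fold higher. Ag.UNKN.186.1_s_at was at least 800-fold lower and Ag.X.80.0_UTR_a_at at least 206-fold lower at 15 d. The counts were 3572 at 96 h (2167 higher, 1405 lower) and 4016 at 15 d (2485 higher, 1531 lower; 4235 with the arrays of the shared scan day alone). Median scaling turned the splits to 1571 higher and 1974 lower at 96 h, and to 1734 higher and 2227 lower at 15 d. The 96 h and 15 d females were also older than the non-blood-fed females, which were sampled 3 d after emergence. The 96 h arrays were scanned on another day and carried the mark of a repeated in vitro transcription.

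**Figure D2:**
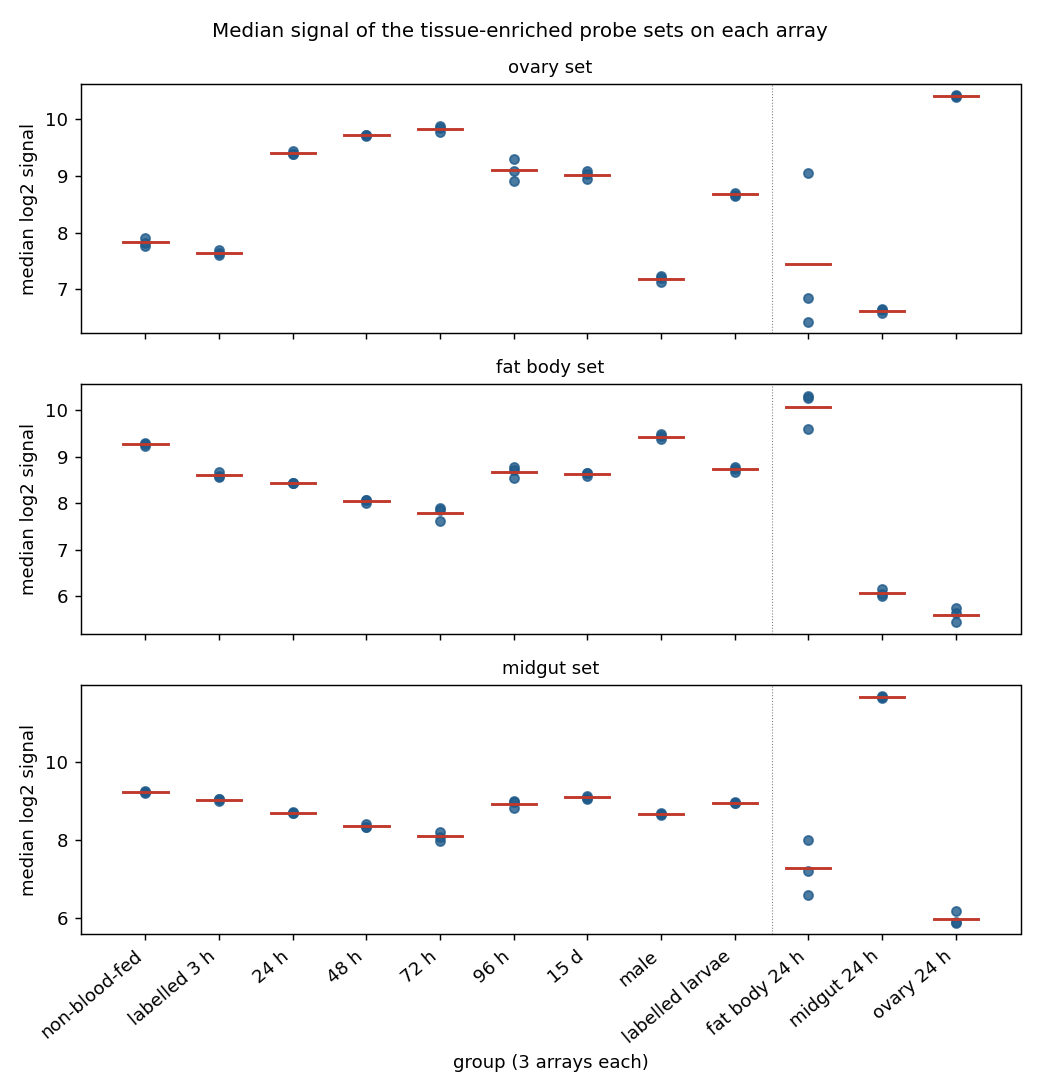
Each point is the median log2 signal of a tissue set on 1 array, and each red line the mean of the 3 arrays of a group, for the ovary set (1441 probe sets), the fat body set (783) and the midgut set (838). In whole females the ovary set is highest at 72 h, at 9.83, and in the dissected groups 1 fat body array, at 9.04, lies near the whole females.

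The arrays labelled 3 h had lower correlations with the other whole-body groups than any of those groups had with non-blood-fed females. Their mean r was 0.687 with non-blood-fed females, 0.607 with 24 h and 0.632 with males, whereas non-blood-fed females and males correlated at 0.855. In the ovary set 203 members were lower and 84 higher, and the set as a whole did not pass (camera adjusted p = 0.571, and adjusted p = 0.960 with an estimated correlation). The fat body set had 286 members lower and 125 higher (camera adjusted p = 0.00116, and adjusted p = 0.412 with an estimated correlation). The midgut set was split, with 225 lower and 188 higher (camera adjusted p = 0.985). Ag.2L.2455.0_CDS_at measured 47600 ± 3170 in the arrays labelled 3 h against 14.8 ± 5.42 in non-blood-fed females (SD, n = 3), at least 612-fold higher, and Ag.3L.1558.0_CDS_at 39900 ± 2700 against 23.5 ± 8.66, at least 513-fold higher. Ag.2L.245.0_CDS_at fell at least 397-fold and Ag.2L.35.0_CDS_a_at at least 245-fold. The comparison called 3993 probe sets, 1720 higher and 2273 lower, and 4177 with the arrays of the shared scan day alone. Whether these samples are females 3 h after blood stays open, and so does each direction given here.

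The arrays labelled larvae, by contrast, were close to adult females. Their mean r was 0.883 with non-blood-fed females, 0.889 with 24 h, 0.911 with 96 h and 0.905 with 15 d. In the ovary set 466 members were higher than in non-blood-fed females and 5 lower, with a relative median of 0.94 (camera adjusted p = 5.17e-18, and adjusted p = 0.274 with an estimated correlation). The fat body set had 176 members lower and 41 higher (adjusted p = 0.175 with an estimated correlation), and the midgut set 125 lower and 70 higher (adjusted p = 0.421 with an estimated correlation). Ag.3R.1113.0_CDS_at was at least 20.7-fold higher, at 1670 ± 533 against 29.4 ± 2.35 (SD, n = 3), and Ag.3L.597.0_CDS_at measured 2680 ± 553 against 66.2 ± 52.8, where 1 of 3 non-blood-fed arrays lay above the limit. Ag.3R.180.0_CDS_at and Ag.3R.231.0_CDS_at fell to 49.9 ± 13.8 and 59.3 ± 43.8, each above the limit on 1 of 3 arrays. The comparison called 2284 probe sets, 1295 higher and 989 lower, and 2576 with the arrays of the shared scan day alone. Directions for a stage difference cannot be drawn while the identity of these arrays is open.

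**Figure D3:**
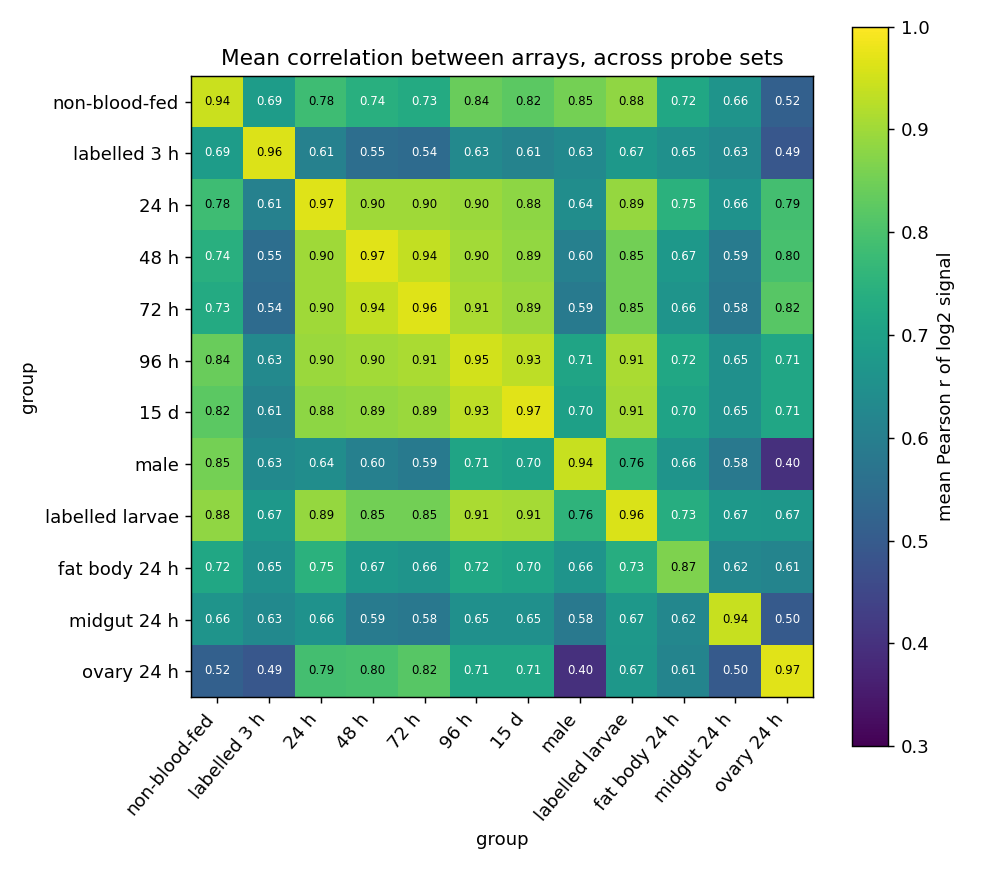
Each cell gives the mean Pearson r across 14822 probe sets between the arrays of a pair of groups, with within-group pairs on the diagonal. The arrays labelled 3 h reach at most 0.69 with any other group, while those labelled larvae reach 0.91 with 96 h.

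Males and non-blood-fed females, both sampled 3 d after emergence, differed in 2142 probe sets, 774 higher and 1368 lower in males, and in 2352 with the arrays of the shared scan day alone. The actin ratio was 2.63 ± 0.445 in males (SD, n = 3). Of the ovary set 387 members were lower in males and 36 higher, with a relative median of -0.56 (camera adjusted p = 4.75e-08, and adjusted p = 0.451 with an estimated correlation). The midgut set had 187 members lower and 46 higher (adjusted p = 0.421 with an estimated correlation), and the fat body set 78 higher and 61 lower (adjusted p = 0.454 with an estimated correlation). Ag.UNKN.223.1_s_at measured 40400 ± 2190 in males against 82.2 ± 122 in females, and Ag.UNKN.303.0_CDS_at 27500 ± 1000 against 55.3 ± 83.2 (SD, n = 3). Each lay above the limit on 1 of the 3 female arrays. Ag.3R.19.0_CDS_at was at least 200-fold lower in males, at 6.23 ± 1.77 against 20300 ± 2280, and Ag.2L.35.0_CDS_a_at at least 154-fold lower. On the X chromosome 45 of 1237 probe sets were higher in males (3.64%), against 670 of 12357 on the autosomes (5.42%), an odds ratio of 0.659 with a 95% interval of 0.473 to 0.897 (Fisher's exact test, adjusted p = 0.0146). After quantile normalization the exact test's adjusted p was 0.0779, the highest of a range of 0.0151 to 0.0779 over the alternatives. Probe sets lower in males made up 10.3% on the X and 9.53% on the autosomes (exact test, adjusted p = 0.627).

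Among the dissected tissues, the ovary differed from the mean of the others in 8190 probe sets, 4026 higher and 4164 lower. Quantile normalization gave 3989 higher and 3185 lower, with the median of all probe sets at 0.03 in place of -0.22. Higher in ovary were Ag.3R.238.0_CDS_a_at, at 10400 ± 245 in ovary, 11 ± 8.13 in midgut and 1080 ± 1610 in fat body (SD, n = 3), and Ag.2R.2943.0_CDS_at, at 4470 ± 185, 9.77 ± 4.10 and 377 ± 633. They were at least 64.7-fold and 59.3-fold higher, and 2 and 1 of the fat body arrays lay above the limit. Ag.2L.395.0_CDS_a_at was at least 997-fold lower in ovary, where it measured 26.2 ± 12.5 against 36700 ± 8730 in fat body and 52500 ± 11500 in midgut. Ag.3L.198.0_CDS_at was at least 245-fold lower, at 5.52 ± 0.681. X-linked probe sets were less often higher in ovary, with 232 of 1237 (18.8%) against 3598 of 12357 on the autosomes (29.1%), an odds ratio of 0.562 with a 95% interval of 0.483 to 0.652 (Fisher's exact test, adjusted p = 3.27e-14). Midgut and ovary shared a scan day, and ovary against midgut alone called 8205 probe sets, 4414 higher.

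The midgut differed from the mean of fat body and ovary in 6620 probe sets, 2545 higher and 4075 lower. Median scaling gave 3142 higher and 3337 lower, with the median of all probe sets at 0.01 in place of -0.23. Ag.2R.927.0_CDS_a_at reached 114000 ± 15200 in midgut, against 11.7 ± 5.32 in ovary and 1650 ± 2810 in fat body (SD, n = 3), where 1 of 3 arrays lay above the limit, at least 1420-fold higher. Ag.3R.211.0_CDS_at reached 108000 ± 10100, against 41.6 ± 13.4 in ovary and 500 ± 853 in fat body, with 2 of the 6 other arrays above the limit. Ag.2R.291.0_CDS_s_at was at least 106-fold lower in midgut, at 16.1 ± 15.1, and Ag.2R.721.0_CDS_s_at at least 342-fold lower, at 52.7 ± 26.3.

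The fat body differed from the mean of midgut and ovary in 5441 probe sets, 3118 higher and 2323 lower. Ag.3L.14.0_CDS_at measured 10600 ± 2820 in fat body against 10.5 ± 1.93 in midgut and 5.98 ± 2.11 in ovary (SD, n = 3), at least 160-fold higher, and Ag.2L.591.0_CDS_a_at 10100 ± 2670, at least 151-fold higher. Ag.2R.911.0_CDS_at was lower, at 65.9 ± 88.2 against 2990 ± 1470 in midgut and 1600 ± 76.2 in ovary, with 1 of 3 fat body arrays above the limit. Ag.3R.2682.0_at was at least 8.98-fold lower. Fat body replicate 1 stood apart: it correlated with ovary replicate 1 at 0.786, against 0.553 and 0.520 for replicates 2 and 3, and its ovary set median was 9.04 against 6.85 and 6.43. Without it the comparison called 6705 probe sets, 3602 higher and 3103 lower. Median scaling of all arrays gave 2446 higher and 3103 lower, and quantile normalization 2388 higher and 3079 lower.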

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

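The tests in this part of the 3 h and larvae labels, of the midgut set and of the background were chosen after the result was seen, while those of the ovary share, the scaling and the other splits of the arrays were written down before. For the 3 h and larvae labels, the criteria for an exchange and for right labels were also made stricter after their values were known. Under the earlier criteria, which left out the counts of the other adult groups and took any clear rise of the ovary set over non-blood-fed females as evidence against right labels, the same values had counted for an exchange and against right labels. For fat body replicate 1, the difference between the ovary and midgut sets and the background limit replaced a first test on the midgut set alone, whose value lay within the spread of the replicates.

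The change against non-blood-fed females differed between 24 h and the arrays labelled 3 h in 6022 probe sets, by a direct limma contrast of the groups. It differed between 48 h and 24 h in 1128, between the arrays labelled larvae and 24 h in 2141, and between the arrays labelled larvae and those labelled 3 h in 4333. Between 72 h and 24 h it differed in 1359 and between 15 d and 96 h in 677, but in each of these pairs the groups were scanned on different days, so day and group cannot be told apart. Probe sets outside the mosquito comparisons that lay above the limit on all arrays of a group were also set against non-blood-fed females. Of those with numeric identifiers, 21 were higher in midgut, 11 in fat body, 6 in the arrays labelled larvae, 3 at 24 h and 2 in the arrays labelled 3 h. The 3 that were higher at 24 h had a median log2 change of 2.85 there, 5.04 in midgut, 2.82 in the arrays labelled larvae, 1.88 in fat body and 0.53 in the arrays labelled 3 h, and their organism was not given in the sources used here. In the other direction, 1 numeric probe set was lower at 24 h, 1 at 48 h, 2 at 72 h, 1 in fat body and 2 in ovary. Of those named by an accession, 33 were higher in fat body, 12 in midgut and 12 in the arrays labelled 3 h, 7 at 15 d, 6 in ovary, 5 at 72 h and 5 in the arrays labelled larvae, 4 each at 24 h, at 48 h and in males, and 2 at 96 h. More of them were lower in most groups: 25 at 72 h, 24 in ovary, 20 in midgut, 16 at 48 h, 14 each at 24 h, at 15 d and in the arrays labelled 3 h, 13 in fat body, 8 in males, 6 at 96 h and 5 in the arrays labelled larvae. Of those with a Plasmodium identifier, 14 were higher in midgut, 10 in fat body, 3 in males, 2 in ovary and 1 each at 48 h, in the arrays labelled 3 h and in those labelled larvae, while 8 were lower in ovary, 7 at 72 h, 4 at 15 d, 3 each at 48 h, at 96 h and in fat body, and 1 each in males and midgut. Lower probe sets lay above the limit on all arrays of the non-blood-fed females. The dissected tissues and the 72 h and 96 h groups were scanned on other days than the non-blood-fed females, so for these counts too day and group cannot be told apart.

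The arrays labelled 3 h had low correlations with the other whole-body groups, and those labelled larvae had high ones with adult females. Of the mosquito probe sets above the limit on every array of the other adult whole-body groups, 115 lay above it on no array labelled 3 h and 2 on no array labelled larvae, against 0 to 7 for each of the 6 other female groups and 219 for males. The 115 thus lay outside the other female groups, as an exchange would have it. With the other female groups alone as the reference, the count was 197 for the arrays labelled 3 h and 236 for non-blood-fed females, whose reference is all blood-fed. It was 2 for the arrays labelled larvae, as an exchange would have it, and 0 to 6 for the other blood-fed groups. With males in the reference, non-blood-fed females fell to 7, so their 236 do not account for the 115. The counts also depend on the background limit, which averaged 102 in males, 78 in non-blood-fed females and 63.8 in the arrays labelled 3 h. By the stricter criterion the 115 had to exceed the count of every adult group, males included, so an exchange stays open. The reference for the 219 was females alone, however, so it is no like standard for arrays labelled as females. Conversely, 93 probe sets lay above the limit on all arrays labelled 3 h and on no array of the other adult groups. For the arrays labelled larvae 1 did so, against 0 to 12 for the 6 other female groups and 32 for males. Larvae that hold 1 probe set apart from adults and miss 2 argue against every label being right, without settling what the arrays are. The ovary set of the arrays labelled larvae lay 0.85 above that of non-blood-fed females on the log2 scale (pooled SD 0.05). It was chosen against fat body and midgut alone, and no other larvae were measured, so its level decides nothing. The 3 numeric probe sets that rose at 24 h, by a median of 2.85, also went the way of an exchange. Their median change was 2.82 in the arrays labelled larvae, with 2 of them called, and 0.53 in those labelled 3 h, with 0 called. In the other whole-body groups it was at most 0.43. With only 3 members, of an organism not given, they do not settle the labels. A difference of scan day is argued against, since both groups shared the scan day of the non-blood-fed females. The actin ratio, at 1.41 in the arrays labelled 3 h and 1.33 in those labelled larvae, lay below the 2.08 of non-blood-fed females. It lay within the wide range of that day's groups, 1.33 to 2.63, which decides little. At 24 h, 48 h and 15 d, however, similar ratios of 1.33 to 1.43 went with a mean r of 0.742 to 0.824 with non-blood-fed females. The ratio therefore does not set the arrays labelled 3 h apart. The exchange is a hypothesis found and tested on the same data, and under it the counts of 3993 and 2284 would trade places.

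Fat body replicate 1 lay close to the ovary arrays. Of the 1710 ovary probe sets chosen without this array, 1661 were higher in it than in the mean of replicates 2 and 3, by a median share of 29.8% of the ovary signal (quartiles 19.7% and 44.0%). Ovary RNA in this sample may account for that, but 69.6% of the probe sets lay within 2-fold of the median share, short of the 75% named beforehand and above the 50% that would have excluded it, so this explanation stays open. A general admixture of other tissues would raise the ovary and midgut sets alike, but the ovary set minus the midgut set lay 3.11 above the mean of replicates 2 and 3 on the log2 scale, and these were 1.19 apart. The midgut set alone, at -0.64, decides nothing, since the fat body set differed by -0.74 too. A raised background is argued against by the background limit, which was 71.6 in replicate 1 against 137 and 132 in replicates 2 and 3. The scaling of the array is argued against by quantile normalization, after which the median rise was 2.11, against 1.98 on the deposited values. No biological explanation was tested, since the labels name no difference between the replicates.

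Other splits of the same arrays into groups of the same sizes were counted for each comparison. With 3 arrays against 3 only 10 splits exist, too few for a share under 0.05. In each of these 9 comparisons, 1 split, the real one, reached the real count. The highest other count was 6 for the arrays labelled 3 h (real 3993), 1 for 24 h (5418), 4 for 48 h (6208), 1 for 72 h (6884), 4 for 96 h (3572), 2 for 15 d (4016), 6 for 96 h against 72 h (1635), 28 for males (2142) and 13 for the arrays labelled larvae (2284). For the F test, 1 of 100 drawn splits, the real one, reached the real 10705, and the highest other gave 5577. Chance in the grouping of these arrays is argued against, at the smallest share that 100 splits can give. A difference between cohorts, which the labels do not give, is not excluded. Of 100 drawn splits of the tissue arrays, 1, the real one, reached the real 8190 of the ovary, with 7975 as the highest other. That other split also had the 3 ovary arrays as its first group. The margin between these 2 splits thus shows only how the fat body and midgut arrays were divided. Here too chance in the grouping is argued against at the smallest possible share, while a difference between cohorts is not excluded. For fat body 4 of 100 splits reached the real 5441, with 7946 as the highest other. For midgut 4 of 100 reached 6620, with 7944 as the highest other, but 6 did in a draw that counted mirrored splits apart, so for midgut the share lies near 0.05 and chance is not firmly excluded. The other fat body splits as large placed the 3 midgut arrays (5988), the 3 ovary arrays (7946), or 2 ovary arrays and 1 fat body array (5537) in the first group. In all 3 of the other midgut splits as large, the first group was the 3 ovary arrays, so these counts point to a structure of the samples, the difference of the ovary from the other tissues.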

How the results depend on the processing

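The scan-day fits of the F test and of the tissues, the F test without the arrays labelled 3 h, and every alternative for the tissue sets and the X chromosome were chosen after seeing the data, while the others were planned. Of 243 alternative counts of calls, 234 lay within 1.5 times the reported count. Without a fold minimum the counts rose, by construction, to 6152 for the arrays labelled 3 h, 8233 at 24 h, 6299 at 96 h, 6778 at 15 d, 4102 for 96 h against 72 h, 4001 for males, 4513 for the arrays labelled larvae and 8722 for fat body. Leaving out each array in turn gave 1080 to 1902 calls for 96 h against 72 h, the lowest without replicate 1 of 96 h, and the cause was not tested. All 688 values of named probe sets under the alternatives kept their direction and stayed past the threshold. With the replicate number as a block, 5420 probe sets were called at 24 h against 5418 without it, 1618 against 1635 for 96 h against 72 h, and 10678 against 10705 in the F test; 5384 of the 5418 calls and 10622 of the 10705 were shared between the fits. The block moved no count by over 1.5 times and ended no call of a named probe set, a tissue set or an odds ratio of the X chromosome. Arrays correlated best with their own number in 24 of 63 cases over the time course, and same-numbered arrays at -0.07 to 0.08, so the numbers did not pair the samples. The 25 set calls that passed with the preset correlation were lost with an estimated one, at the same medians, and the other set alternatives changed no call. The estimate, 0.419 for ovary, 0.106 for fat body and 0.115 for midgut, came from all arrays, fat body replicate 1 included. The ovary set's array medians had an SD of 1.4 in fat body, against 0.01 to 0.19 in the other groups. No estimate without that array was made, so its part in the lost calls was not tested. Of 120 odds ratios for the X chromosome, 5 gained the threshold without a fold minimum. Another 5, all of higher calls, lost it in the same direction: after quantile normalization 15 d (0.873), males (0.733) and the arrays labelled larvae (0.804), and after median scaling 96 h (0.855) and 15 d (0.801). The gene list alternatives were not run, since no probe set could be named. A scan-day block could not be fitted, since each group lay in 1 scan day, nor within-day fits for 72 h and 96 h against non-blood-fed females or for fat body. Low signals limit the rest: the background limit averaged 113 ± 36.2 (SD, n = 3) in fat body and 41.9 ± 3.12 at 15 d.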

Other observations

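All tests in this part were chosen after the data had been seen. Probe sets on the X chromosome were called higher less often than those on the autosomes in 9 of 12 comparisons at an adjusted p under 0.05 by the exact test, and in 15 d, males and the arrays labelled larvae the threshold was missed after quantile normalization, as it was at 96 h and 15 d after median scaling. These included males (odds ratio 0.659) and the arrays labelled 3 h (odds ratio 0.785, exact test, adjusted p = 0.0339), where the ovary set was not higher. Lower calls in the arrays labelled 3 h were more frequent on the X, with an odds ratio of 1.33 (exact test, adjusted p = 0.000921), and those in midgut and fat body less frequent, with 0.699 and 0.768 (exact tests, adjusted p = 1.34e-06 and 0.0078). At 24 h 174 of 1237 X-linked probe sets were higher than in non-blood-fed females (14.1%), against 2691 of 12357 autosomal ones (21.8%), an odds ratio of 0.588 with a 95% interval of 0.495 to 0.695 (Fisher's exact test, adjusted p = 4.07e-10). At 48 h the odds ratio was 0.621 (exact test, adjusted p = 1.46e-09) and at 72 h it was 0.614 (exact test, adjusted p = 3.07e-10). For probe sets called lower at these times, the odds ratios were 0.978, 1.01 and 1.02 (exact tests, adjusted p = 0.883, 0.909 and 0.883). Among probe sets with a mean signal of at least 200, the median log2 change in ovary against fat body and midgut was -0.279 for 724 X-linked and 0.273 for 7469 autosomal probe sets. The same medians for males against non-blood-fed females were -0.010 and 0.021. Probe sets of 1 gene or of neighbouring genes are not independent, so these p-values are too small. For higher calls at 15 d the odds ratio of 0.827 (exact test, adjusted p = 0.0449) was 0.873 after quantile normalization (exact test, adjusted p = 0.222) and 0.801 after median scaling (exact test, adjusted p = 0.0545). The threshold was missed in both, in the same direction, and after median scaling the odds ratio lay further from 1. The adjusted p ranged from 0.00351 to 0.222 over the alternatives.

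Probe sets of a single group were counted among the whole-body groups. The arrays labelled 3 h held 87 mosquito probe sets that lay above the limit on all 3 of their arrays and on no array of another whole-body group. Males held 20, and those labelled larvae held 1. In the other direction, 130 probe sets lay above the limit on every array of the other whole-body groups and on no male array, and 110 did so for the arrays labelled 3 h. The limit itself averaged 102 ± 19.4 in males and 63.8 ± 6.85 in the arrays labelled 3 h (SD, n = 3), against 41.9 to 78 in the other whole-body groups. A higher limit raises such a count of absences, and its part in them was not tested.

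The fat body arrays also differed in the midgut set, with array medians of 6.61, 7.22 and 8.01 on the log2 scale for replicates 1, 2 and 3. Their 3' to 5' actin ratios were 3.25, 4.69 and 4.20.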
